A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

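Total RNA from 8 independent yeast cultures, 4 per iron level, was extracted with Trizol, labelled with biotin and hybridised to Affymetrix yeast arrays that carry probe sets for S. cerevisiae and S. pombe, per the labels' protocols and the platform annotation. The deposited values are MAS5 signal intensities on a linear scale, 1 value per probe set and array, and MAS5 is the only tool in the submitters' processing notes. The settings for background and scaling are not given in the sources used here. On each of the 8 arrays the mean of the deposited values after trimming 2% at each end was 500.2, so they had been scaled to a common level, and no further scaling was applied in the main analysis. Such scaling sets the average of each array equal and hides a change in the total mRNA per cell. The brightest probe set of each array read 6597 to 7706, and changes of genes near this level can be compressed. Such genes include 323 tested genes with a mean over 4000 across all 8 arrays, among them 14 of 19 glycolysis and 10 of 14 purine genes. Genes near this level in only 1 condition can be compressed too and need not be in this count.

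Of 10928 probe sets, 5498 matched 1 S. cerevisiae gene through the platform's gene identifier and the RefSeq gene table of assembly R64, which was used only for names. A further 1746 carried other gene identifiers of the platform table with symbols in the S. pombe style and served as background, 1 was paired with several genes, 3517 had no gene in the platform table and 166 were control probe sets. Array signals have no named genome build in the sources used here, so no coordinates are given. Where a gene had several probe sets (46 tested genes), the brightest over all arrays was used, and no such gene had probe sets that differed by over 1 on the log2 scale. Of the tested probe sets, 110 carry the suffix for probes shared with similar sequences. A gene was tested when its mean signal over the 8 arrays exceeded 5.48, the 95th percentile of the S. pombe probe sets. This left 5412 of 5449 genes, with 37 below background.

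Signals were taken as log2(signal + 1), and low iron was compared with high iron with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), two-sided, over all 8 arrays with no other term. P-values were adjusted by the Benjamini-Hochberg method over the 5412 genes, with a threshold of 0.05. A fold change is on the log2(signal + 1) scale and understates the change of dim genes. A gene not above the array's own background on any array of a condition has only a bound there. Groups of genes were tested with camera (preset correlation of 0.01), with p-values adjusted over the 41 lists, and again with a correlation estimated from the data and with fry, which tests whether a list's genes move one way without comparing them with other genes. The lists, fixed before the data were examined, cover 697 genes, of which 672 were tested, and the result of each is given in the report. Ribosomal protein lists were made from gene name patterns, so that the cytosolic one also holds RPP1, a subunit of ribonuclease P, and the mitochondrial one MRP8, which is not an established ribosomal protein. Array measures were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

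The genes named in the text follow a rule set before the data were examined: the 10 largest rises and the 10 largest falls among genes past the threshold whose conditions did not overlap, 24 genes chosen for their known part in iron metabolism whatever their result, and up to 4 members per list with the lowest adjusted p, not all of which are printed. Genes outside it, chosen after their values were seen, are ATX1, MRS3, NDE2, MET10, MRP8 and FIT3 in the report and its plots, the pheromone genes FUS1, AGA1, PRM1 and PRM4, and HAP1, AFT1, FRM2, HBN1, ZTA1, VMR1 and CAD1. A list of 22 pheromone response genes was also chosen after the data were seen.

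The procedure was tested on simulated data with 200 changed genes among the 5412. It recovered 78% of genes changed by 0.5 on the log2 scale, 92% of those changed by 1 and 100% of those changed by 2 or 4, and called 3 of 5212 unchanged genes (0.0576%). In the data 2133 genes were called, many more than were changed in the simulation. The p-value adjustment depends on that share, so these rates need not hold for the data. Both lists shifted by 0.5 in the simulation were called, and no list that shared no gene with them was. The simulated genes varied independently of each other, so the list test was not tried on correlated genes. In the data the estimated correlation within a list reached 0.81, for siderophore and cell wall genes.

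Alternatives set before the data were examined were pseudocounts of 16 and 64, quantile normalization, median centring, no filter and a filter at the 99th percentile of background (9.21), raising values to background, no intensity trend, array weights, the mean of a gene's probe sets, leaving out each array in turn, and a block from the numbers in the sample descriptions. These numbers form 1 unbroken series of 8, which was divided into the first 3 and the last 5 because each part goes from low to high iron, and the labels name no such batches. Leaving out low-iron array 1 with high-iron array 1, and low-iron arrays 1 and 2, were chosen after seeing the data, as was a fit with the array number as a block. Array numbers follow the order of deposit, and the labels do not pair the cultures.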

Results

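Total RNA was profiled from 8 cultures of the Saccharomyces cerevisiae laboratory strain DBY7286 on Affymetrix yeast arrays, 1 array per culture. Every culture held 1 mM Ferrozine, a chelator of ferrous iron, and 1 µM copper at pH 6.1. In 4 independent cultures the ferrous iron supplied was 10 µM (low iron) and in the other 4 it was 300 µM (high iron), and all were grown at 30 °C for about 18 h to an A600 of 0.5. The question was how yeast metabolism responds when iron is scarce, and the only comparison in its design is low against high iron. Array signals had a common scale, with a trimmed mean of 500.2 on each array. Between 98.7% and 99.3% of the S. cerevisiae probe sets lay above the background given by Schizosaccharomyces pombe probe sets of the same array. This background was only 5.4 to 8.06 signal units, so a signal above it does not by itself show expression. The number of arrays, 4 per condition, limits the precision of each value.

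Between low and high iron 2133 of the 5412 genes tested differed (39.4%), of which 907 were higher and 1226 lower in low iron (limma, adjusted p under 0.05). Which direction held more genes turned with the scaling, with 1181 higher and 1091 lower under quantile normalization and 1138 and 1072 under median centring. Most of these changes were small, with a median absolute log2 change of 0.39, and 223 genes differed at least 2-fold, 74 of them higher and 149 lower in low iron, a count that came to 135 on the log2(signal + 64) scale. At least 4-fold differences were seen for 24 genes that rose and 22 that fell. Among the largest rises were those of FIT1 and FRE2, and among the largest falls those of CYC1 and CCP1. In 2086 genes (38.5%) the 4 low-iron values did not overlap the 4 high-iron values, where chance gives 2.86%. The first principal component held 75.8% of the variance and separated the conditions, and the second held 12.1% and separated low-iron arrays 1 and 2 from low-iron arrays 3 and 4. Correlations across genes between arrays were 0.983 to 0.996 within low iron, 0.994 to 0.997 within high iron and 0.954 to 0.969 between the conditions. The median signal of ribosomal RNA control probe sets was lower in low iron, at 3082 ± 548 against 3998 ± 244 (SD, n = 4; two-sided exact permutation test, p = 0.0286, the smallest this design allows). It was lowest on low-iron arrays 1 and 2 (2682 and 2567). The permutation p-value was not adjusted for the other array measures compared. Single rRNA probe sets had log2 changes from 1.9e-05 to -1.15, so the difference was not uniform. On low-iron array 1 and high-iron array 1, 4 reporter-class probe sets that read 381 to 3144 on the other arrays read 0.444 to 25.9.

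Genes on the lists for siderophore iron and for reductive iron uptake rose together in low iron. All 7 tested genes for siderophore-iron transport and for the cell wall mannoproteins that retain siderophore iron rose, with a median log2 change of 3.42. All 11 genes on the reductive uptake list, which also holds reductase relatives and copper supply genes, rose, with a median of 1.66. FIT1 (YDR534C), a cell wall mannoprotein, went from 113 ± 55.8 in high iron to 5569 ± 482 in low iron (SD, n = 4), a log2 change of 5.71 ± 0.242 (SE; limma adjusted p = 6.78e-08). The metalloreductase gene FRE2 (YKL220C), whose product reduces ferric iron at the cell surface, rose 29.0-fold from 120 ± 8.91 to 3523 ± 378 (adjusted p = 2.44e-10). FET3 and FTR1, which encode the multicopper ferroxidase and the permease of high-affinity ferrous iron uptake, rose 2.51-fold from 1962 ± 147 to 4930 ± 430 and 3.16-fold from 1796 ± 235 to 5653 ± 348. The low-iron signals of FIT1, FET3 and FTR1 lie close to the top of the range, where the brightest probe set of each array read 6597 to 7706. Their folds can therefore be compressed.

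**Figure D1:**
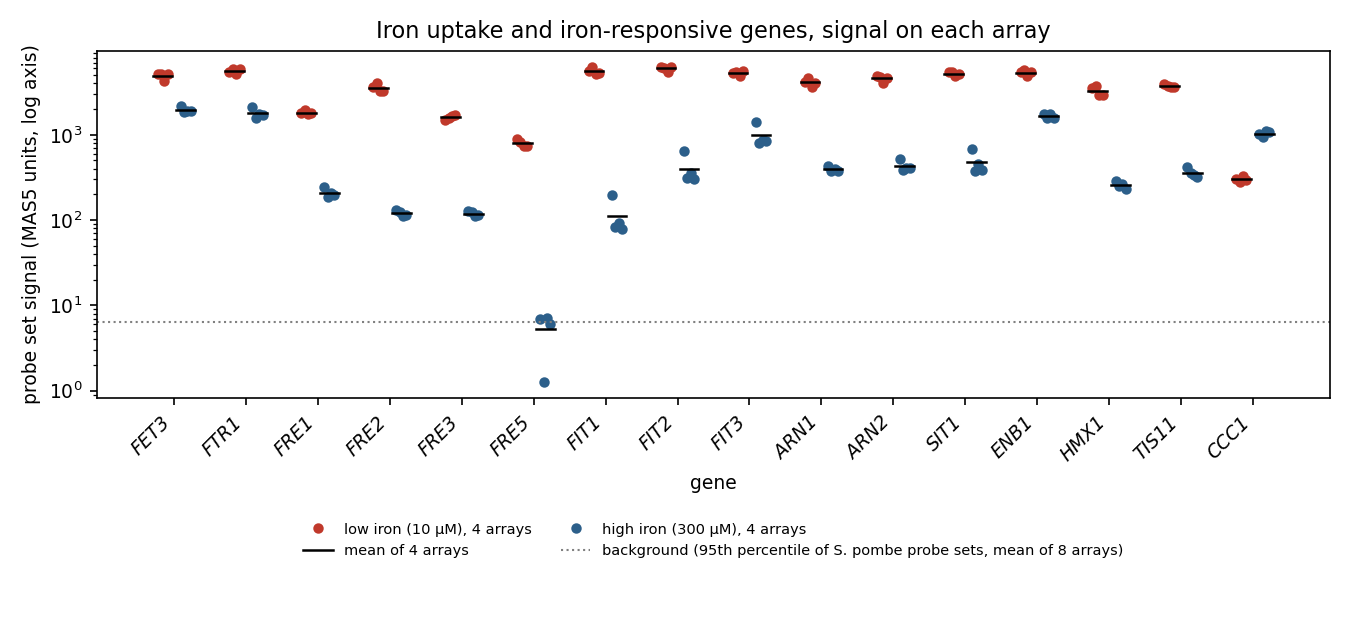
Probe set signal (MAS5 units, log axis) of 16 iron uptake and iron-responsive genes on each of the 4 low-iron arrays (red) and 4 high-iron arrays (blue), with black bars at the means and a dotted line at the background. For 15 of these genes every low-iron array lies above every high-iron array, while CCC1 lies at 303.4 in low iron against 1034 in high iron.

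Other members of these groups moved the same way. FIT2 rose by 3.97 on the log2 scale, SIT1, ARN2 and ARN1, 3 siderophore-iron transporters, by 3.50, 3.42 and 3.37, and the reductase genes FRE3 and FRE1 by 3.74 and 3.12. In low iron FIT2, SIT1, ARN2 and ARN1 read 6026, 5220, 4599 and 4123, so their folds and their list's median can be compressed too. CCC2, a copper pump that loads the ferroxidase, rose by 2.81, and the copper chaperone gene ATX1 by 0.43. FRE5 (YOR384W), a reductase family member, reached 794 ± 69.6 in low iron against 5.34 ± 2.76 in high iron, where it was above background on 3 of 4 arrays, a log2 change of 7.13. As many genes, 7 and 11, passed when adjusted over the list alone. Both lists moved beyond the other genes (camera adjusted p = 8.04e-11 for siderophore and cell wall genes and 8.46e-14 for reductive uptake). The call for siderophore and cell wall genes was lost with an estimated correlation between genes (adjusted p = 0.187 with an estimated correlation), while that for reductive uptake held (adjusted p = 0.0401 with an estimated correlation).

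Of 15 genes that mobilise or spare iron under the iron-responsive factors Aft1 and Aft2, 13 rose and 1 fell in low iron, with the same counts adjusted over the list alone and a median log2 change of 1.18 (camera adjusted p = 7.0e-12; adjusted p = 0.171 with an estimated correlation). HMX1, the haem oxygenase, rose 12.6-fold from 259 ± 21.6 to 3287 ± 421, and TIS11, an mRNA-binding protein that promotes decay of transcripts for iron-using pathways, rose 10.4-fold from 359 ± 44.4 to 3742 ± 150 (SD, n = 4; limma adjusted p = 2.25e-09 and 1.57e-09). Its relative CTH1 fell by 0.48 on the log2 scale (adjusted p = 0.00134). LSO1 (YJR005C-A), a small gene of the iron regulon, read 382 ± 141 in low iron and was not above background on any high-iron array, a difference of at least 48-fold. Genes that move iron out of the vacuole or into mitochondria also rose, SMF3 by 0.73 and MRS4 by 1.16, and MRS3, the paralogue of MRS4, read 0.07 and did not pass. On the log2(signal + 64) scale, the changes of FRE5 and LSO1, which are dim in high iron, came to 3.63 and 2.70.

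Genes of high-iron growth and of copper uptake gave a mixed picture. Of 4 genes that depend on Yap5, a factor active in high iron, 3 fell in low iron, and 3 when adjusted over the list alone, although the list did not pass (camera adjusted p = 0.0689). CCC1, the importer of iron into the vacuole, fell 3.40-fold from 1034 ± 72.2 to 303.4 ± 20.8 (SD, n = 4; limma adjusted p = 5.91e-08), and TYW1, an iron-sulphur enzyme of tRNA modification, fell by 0.80 on the log2 scale. Among the 4 copper uptake genes of the Mac1 regulon 2 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.355). CTR1, the main copper transporter, rose by 0.64, CTR3 fell by 0.42, and FRE1 is shared with reductive uptake. FRE7, dim at 23.7 ± 5.39 in high iron, fell by 0.86, a call that ended in 3 of 22 alternatives (adjusted p up to 0.0858, under quantile normalization) and a change that came to -0.19 on the log2(signal + 64) scale. On that scale CTR3 came to -0.27, and under quantile normalization to -0.26.

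Transcripts of the respiratory chain fell in low iron. Of 23 tested nuclear-encoded genes 22 fell, over all genes and adjusted over the list alone, with a median log2 change of -1.15 (camera adjusted p = 2.59e-13; adjusted p = 0.187 with an estimated correlation). CYC1 (YJR048W), cytochrome c, fell 14.7-fold from 892 ± 82.9 to 62.1 ± 21.0 (SD, n = 4; limma adjusted p = 2.51e-07). CYT1, cytochrome c1, fell 7.09-fold, the second cytochrome c gene CYC7 6.36-fold and RIP1, the Rieske iron-sulphur protein, 5.89-fold. Subunits that hold no iron fell as well, such as COX6 by 1.42 and COX4 by 1.22 on the log2 scale. The gene that did not pass was NDE2, an external NADH dehydrogenase, with a log2 change of -0.19.

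Within the tricarboxylic acid cycle, the falls were largest for succinate dehydrogenase. All 4 of its subunit genes fell, SDH1 from 1032 ± 118 to 139 ± 27.9 (7.46-fold; limma adjusted p = 1.35e-07), and SDH2, SDH3 and SDH4 with log2 changes of -2.51, -1.95 and -1.95. Aconitase, ACO1, fell 1.59-fold from 4922 ± 212 to 3141 ± 586, whereas both isocitrate dehydrogenase genes rose, IDH1 by 0.48 and IDH2 by 0.35. ACO1 in high iron, and IDH1 and IDH2 in low iron (5392 and 5010), read close to the top of the range. Their changes can therefore be compressed and are not directly comparable in size with those of the dimmer succinate dehydrogenase genes. Over the cycle 8 of 16 genes fell and 4 rose, with the same counts adjusted over the list alone and a median of -0.22 (camera adjusted p = 0.0492; adjusted p = 0.664 with an estimated correlation). This list was no longer past the threshold without low-iron array 3 (adjusted p = 0.106), low-iron array 4 (0.0697), high-iron array 2 (0.0659) or high-iron array 3 (0.0568), nor with the mean of probe sets (0.0527). The retrograde response list, which shares ACO1, IDH1 and IDH2 with the cycle, had 5 genes that rose and 1 that fell of 8, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.116).

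Mitochondrial translation and ATP synthesis genes shifted by smaller amounts. Of 66 genes with names of mitochondrial ribosomal proteins 48 fell and 1 rose (54 and 1 adjusted over the list alone), with a median log2 change of -0.31 (camera adjusted p = 2.36e-11; adjusted p = 0.255 with an estimated correlation). MRPL27 fell by 0.60 from 886 ± 27.7 to 583 ± 34.3 and MRPS9 by 0.48 from 1604 ± 37.2 to 1150 ± 39.1 (SD, n = 4; limma adjusted p = 3.9e-05 and 3.93e-05). Of 14 ATP synthase genes 8 fell and none rose, likewise adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0146; adjusted p = 0.335 with an estimated correlation), among them ATP20 at -0.63 and ATP16 at -0.52. The gene that rose, by 0.19, was MRP8, which shares the name pattern but is not an established ribosomal protein. It lost its call in 4 of 22 alternatives, with an adjusted p of up to 0.0667. The median signal of the rRNA control probe sets differed by -916 units, low minus high iron, beside these shifts.

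**Figure D2:**
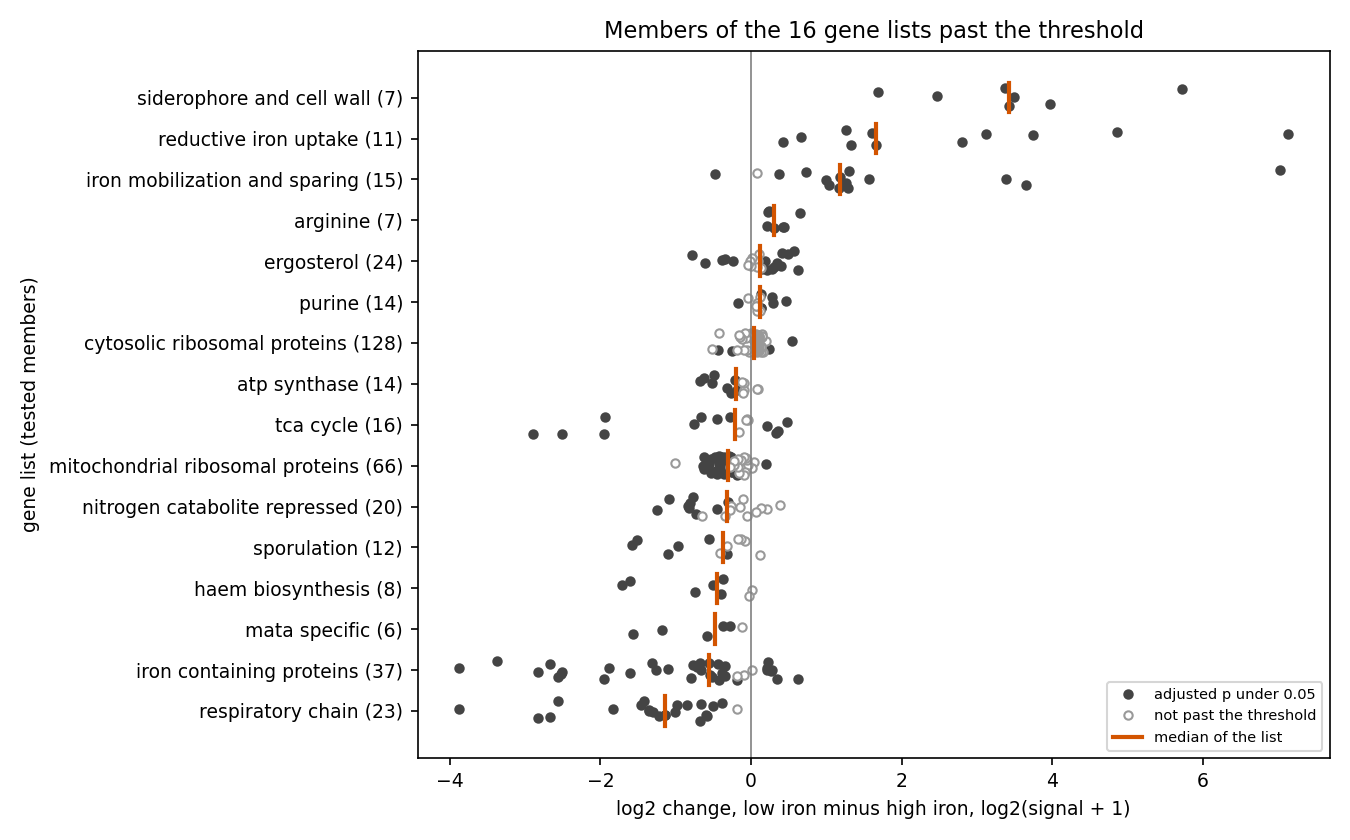
Log2 change (low minus high iron, log2(signal + 1)) of each tested member of the 16 gene lists past the threshold, with filled points for genes with an adjusted p under 0.05, open points for the rest and orange bars at list medians. The medians run from -1.15 for the respiratory chain to 3.42 for siderophore and cell wall genes.

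Genes for proteins that hold iron mostly fell. Of 37 tested genes for haem, iron-sulphur or non-haem iron proteins, 27 fell and 7 rose (28 and 7 adjusted over the list alone), with a median log2 change of -0.56 (camera adjusted p = 3.89e-07; adjusted p = 0.187 with an estimated correlation). The list shares CYC1, CYC7, CYT1 and RIP1 with the respiratory chain and ACO1 and SDH2 with the tricarboxylic acid cycle. CCP1, mitochondrial cytochrome c peroxidase, fell 10.3-fold from 1581 ± 69.8 to 157 ± 51.7 (SD, n = 4; limma adjusted p = 2.76e-07), and the catalase genes CTT1 and CTA1 had log2 changes of -1.95 and -1.32 (-0.98 and -0.60 on the log2(signal + 64) scale). The iron enzymes ERG3 and OLE1, both of lipid synthesis, rose by 0.62 and 0.27, and RNR2, the iron-holding small subunit of ribonucleotide reductase, fell by 0.43. CIR2 (YOR356W), a relative of mitochondrial electron transfer flavoprotein dehydrogenases that is in no list, fell 7.92-fold from 1259 ± 40.4 to 159 ± 23.8 (adjusted p = 1.86e-08).

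Haem synthesis genes fell in low iron. Of 8 genes 6 fell and none rose, the same adjusted over the list alone, with a median log2 change of -0.46 (camera adjusted p = 0.0036; adjusted p = 0.181 with an estimated correlation). HEM15, ferrochelatase, fell 3.28-fold from 2463 ± 207 to 758 ± 147 and HEM13, coproporphyrinogen oxidase, 3.04-fold from 1162 ± 47.9 to 385 ± 61.7 (SD, n = 4; limma adjusted p = 2.83e-06 and 1.48e-06). Iron-sulphur cluster assembly genes went both ways, with 8 of 24 higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.275). The scaffold gene ISU2 rose 2.97-fold from 1179 ± 44.5 to 3516 ± 336, whereas YFH1, frataxin, fell 2.92-fold from 698 ± 50.4 to 242 ± 57.2 and NFU1 fell 2.27-fold.

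Biotin genes moved both ways. BIO2, the iron-sulphur enzyme biotin synthase, fell 3.70-fold from 1741 ± 133 to 470 ± 38.3 (SD, n = 4; limma adjusted p = 5.5e-08), and BIO3 and BIO4, of earlier steps, fell by 0.67 and 0.84 on the log2 scale. VHT1, the biotin permease, rose 2.39-fold from 1803 ± 103 to 4316 ± 383. Of the 6 genes 3 rose and 3 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.83).

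Several genes of amino acid metabolism changed. GLT1, glutamate synthase, an iron-sulphur enzyme, fell 5.75-fold from 2763 ± 210 to 481 ± 55.2 (SD, n = 4; limma adjusted p = 1.86e-08), and GDH3, a glutamate dehydrogenase that makes glutamate without iron, rose 4.50-fold from 249 ± 10.7 to 1129 ± 116 (adjusted p = 2.01e-08). The iron-sulphur dehydratases LYS4, LEU1 and ILV3 fell by 1.10, 0.56 and 0.55 on the log2 scale. BAT2, the cytosolic branched-chain aminotransferase, rose by 1.45, the mitochondrial carrier gene OAC1 by 0.78, and BAP2 (YBR068C), a branched-chain amino acid permease, rose 12.1-fold from 51.5 ± 7.90 to 643 ± 157. As lists, glutamate and glutamine (2 of 5 rose, 1 fell; camera adjusted p = 0.532), branched-chain amino acids (6 of 12 rose, 3 fell; 0.0766) and lysine (3 of 9 rose, 1 fell, or 3 and 2 adjusted over the list alone; 0.385) did not pass.

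Of the remaining amino acid lists, only arginine passed, with all 7 tested genes higher in low iron, also adjusted over the list alone, and a median log2 change of 0.30 (camera adjusted p = 1.93e-04; adjusted p = 0.187 with an estimated correlation). ARG3 rose by 0.65 from 1916 ± 211 to 3010 ± 227 (SD, n = 4; limma adjusted p = 1.74e-04). Histidine genes (3 of 7 rose, 1 fell, likewise adjusted over the list alone; camera adjusted p = 0.0683) and sulphate and methionine genes (5 of 15 rose, 4 fell, or 6 and 4 adjusted over the list alone; 0.275) did not pass. Within the latter, MET5 and MET10, the subunits of the haem and iron-sulphur enzyme sulphite reductase, fell by 0.44 and 0.52.

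Genes used for poor nitrogen sources and for purines gave weaker list shifts. Of 20 nitrogen catabolite repressed genes 9 fell and none rose, also adjusted over the list alone, with a median log2 change of -0.32 (camera adjusted p = 0.0411; adjusted p = 0.664 with an estimated correlation), among them the allantoin genes DAL3 and DAL7 at -0.84 and -0.83 and the ammonium permease gene MEP3 at -1.25. Without low-iron array 3, low-iron array 4, high-iron array 2 or high-iron array 3 the list did not pass (adjusted p = 0.115, 0.107, 0.0659 and 0.0568), nor with the first 3 against the last 5 description numbers as a block (0.0601) or under fry (0.0689). Its median was -0.20 without low-iron array 4, -0.50 without low-iron array 1 (0.00125) and -0.62 without low-iron arrays 1 and 2 (1.08e-04). Of 14 purine and one-carbon genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0144; adjusted p = 0.536 with an estimated correlation), led by ADE16 at 0.47 and the glycine cleavage genes GCV1 and GCV2 at 0.29 and 0.28. The purine call ended under quantile normalization (adjusted p = 0.314) and without low-iron arrays 1 and 2 (0.0631).

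In ergosterol synthesis 11 of 24 genes rose and 5 fell, the same adjusted over the list alone, with a median log2 change of 0.12 (camera adjusted p = 0.0315; adjusted p = 0.664 with an estimated correlation). HMG2, a reductase of the mevalonate branch, rose 1.49-fold from 1203 ± 35.5 to 1788 ± 45.9 and the desaturase gene ERG3 1.54-fold, whereas ERG1 and ERG7, the epoxidase and cyclase of squalene, fell 1.53-fold and 1.72-fold and the haem enzyme gene ERG11 1.30-fold (limma adjusted p = 0.0053). The ergosterol list did not pass without low-iron array 1 (adjusted p = 0.0975), under quantile normalization (0.305), without low-iron arrays 1 and 2 (0.243) or without low-iron array 1 and high-iron array 1 (0.131). In fatty acid and sphingolipid synthesis 3 of 16 genes rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.856), with the iron-dependent hydroxylase genes SCS7 and SUR2 lower by 0.72 and 0.67 and MGA2, a regulator of the desaturase gene OLE1, higher by 0.77.

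Lists of carbon metabolism outside the respiratory pathways did not pass. Glycolysis (2 of 19 rose, 3 fell, or 1 and 2 adjusted over the list alone; camera adjusted p = 0.195), glyoxylate and gluconeogenesis (4 of 10 fell, or 7 adjusted over the list alone; 0.0524), glycogen and trehalose (2 of 15 rose, 3 fell, the same adjusted over the list alone; 0.856) and hexose transport (2 of 6 fell, the same adjusted over the list alone; 0.318) were tested. HXT7, a high-affinity hexose transporter, fell 3.73-fold from 3933 ± 315 to 1225 ± 726 (SD, n = 4; limma adjusted p = 0.00244), with a wide spread between the low-iron arrays. Its probe set carries the suffix for probes shared with similar sequences, so the signal may not be that of HXT7 alone. HXT4 read 3016 ± 215 in high iron against 1641 ± 1040 and did not pass (adjusted p = 0.0674). HXT4 did pass in 5 of 22 alternatives, with an adjusted p as low as 0.0136, and without low-iron arrays 1 and 2 together the log2 change of HXT7 was -1.09 against -1.90 over all arrays.

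Stress and micronutrient lists did not pass as groups. In oxidative stress 3 of 20 genes rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.532), the largest falls being those of CCP1 and the catalases. In heat shock 1 of 15 rose and 7 fell, also adjusted over the list alone (0.0714), led by HSP12, a membrane-associated stress protein, which fell 6.11-fold from 2571 ± 381 to 423 ± 92.0 (SD, n = 4; limma adjusted p = 8.38e-07). Genes of low oxygen split 5 to 5 among 15 (6 and 5 adjusted over the list alone; 0.837). The zinc (1 of 11 rose, 3 fell; 0.472), phosphate (4 of 15 rose, 2 fell; 0.39), kynurenine and NAD (2 of 10 rose, 2 fell; 0.619), ribonucleotide reductase (3 of 7 rose, 2 fell; 0.801) and thiamine and pyridoxine lists (7 of 13 rose, 5 fell; 0.293) had the same counts adjusted over the list alone. Within them ADH4 fell by 1.06, and the pyridoxine genes SNO1 and SNZ1 rose by 1.23 and 1.08 (0.79 for SNO1 on the log2(signal + 64) scale). GTO3 (YMR251W), an omega-class glutathione transferase, rose 11.1-fold from 49.4 ± 8.70 to 550 ± 24.4 (adjusted p = 1.86e-08), and OPT2 (YPR194C), an oligopeptide transporter, fell 9.07-fold from 183 ± 46.8 to 19.1 ± 4.04 (adjusted p = 1.56e-06).

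Several mating genes, among them most tested genes of MATa cells, were lower in low iron. FIG1 (YBR040W), a membrane protein induced by mating pheromone, fell 9.80-fold from 116 ± 13.2 to 11.0 ± 1.94 (SD, n = 4; limma adjusted p = 8.01e-08). Of 6 genes of MATa cells 5 fell, over all genes and adjusted over the list alone, with a median log2 change of -0.48 (camera adjusted p = 7.39e-04; adjusted p = 0.255 with an estimated correlation), among them ASG7 by 1.56, BAR1, the protease that degrades alpha factor, by 1.18, and STE2, the alpha factor receptor, by 0.38 from 5625 ± 175. Of 4 genes of MATalpha cells 1 fell, the alpha factor gene MF(ALPHA)1, from 47.8 ± 8.28 to 10.0 ± 3.76, and STE3, SAG1 and MF(ALPHA)2 did not pass, with log2 changes of -0.09, 0.05 and -0.33 (1 fell adjusted over the list alone; camera adjusted p = 0.408). Of 12 sporulation genes 6 fell and none rose, also adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0215; adjusted p = 0.187 with an estimated correlation), led by SPS1 at -1.59 and SPS4 at -1.52. The sporulation call ended under quantile normalization, where its median was -0.03 (adjusted p = 0.314), and without low-iron arrays 1 and 2 (0.0631). On the log2(signal + 64) scale the changes of FIG1, OPT2 and CYC7, which are dim in low iron, came to -1.26, -1.55 and -1.49. Those of SPS1, SPS4 and MF(ALPHA)1 came to -0.88, -0.93 and -0.59, and the sporulation median to -0.11.

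**Figure D3:**
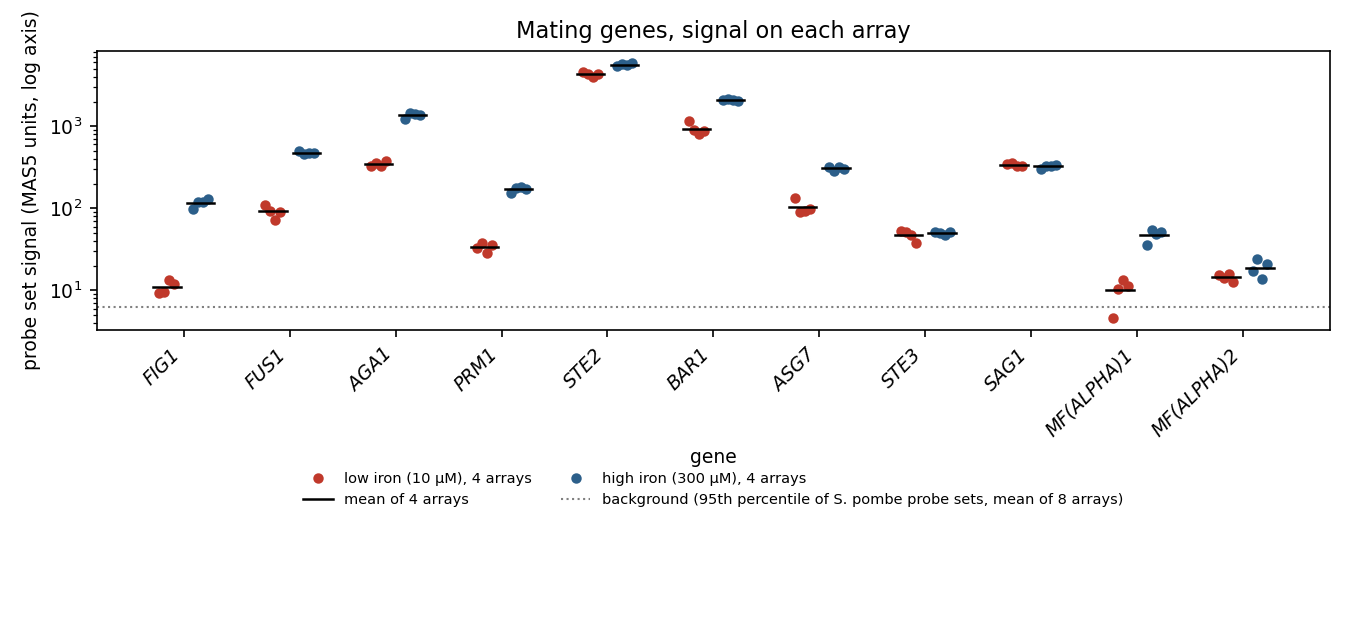
Probe set signal (MAS5 units, log axis) of 11 mating genes on each of the 4 low-iron arrays (red) and 4 high-iron arrays (blue), with black bars at the means and a dotted line at the background. FIG1 lies at a mean of 11.0 in low iron against 116 in high iron, and STE3 at 47.5 against 50.1.

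Few genes of the cytosolic translation machinery passed the threshold. Of 36 ribosome assembly genes none passed in either direction, over all genes or adjusted over the list alone (camera adjusted p = 0.902). Most of these genes spread more between the low-iron than between the high-iron arrays, such as RRP12 with an SD of 403 against 148. Their estimated correlation was 0.775, so the lack of calls does not show that these transcripts kept their level. Of 128 cytosolic ribosomal protein genes 2 rose and 2 fell (2 and 0 adjusted over the list alone), with a median log2 change of 0.04 (camera adjusted p = 0.0406; adjusted p = 0.732 with an estimated correlation), the risers being RPS9A by 0.54 and RPL22B by 0.24 and the fallers RPS10A and RPS10B by 0.25 and 0.44. Of the 128 genes 105 had a mean signal over 4000, close to the top of the range, where changes can be compressed, so small values do not show that these transcripts kept their level. RPS10A lost its call in 6 of 22 alternatives (adjusted p up to 0.164) and RPS10B in 8 (adjusted p up to 0.0915). Both have probe sets with a suffix for probes shared with similar sequences. The list had a median of -0.03 under quantile normalization. It did not pass without low-iron array 1 (adjusted p = 0.0975), low-iron array 4 (0.17), high-iron array 1 (0.175), high-iron array 3 (0.104) or high-iron array 4 (0.0528), with medians from 0.02 to 0.07 when single arrays were left out. It also did not pass with the first 3 against the last 5 description numbers as a block (0.0601), with the mean of probe sets (0.0565), under fry (0.388), without low-iron array 1 and high-iron array 1 (0.324) or without low-iron arrays 1 and 2 (0.163).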

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

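The tests on low-iron arrays 1 and 2, on MATalpha cells, on reporter probe sets and on other splits of the arrays were chosen after the results were seen, and those against random lists matched on signal before their outcome was known. The count of 2133 genes was not matched by another split: of the 35 ways to divide the 8 arrays into 4 and 4, only 1, the real one, gave as many, and the highest other count was 0, which argues against chance division of the arrays. Every other split mixes the conditions, so its count of 0 follows from their separation and does not measure noise. The real split alone, 1 of 35, is the smallest share this test can give.

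The first pattern is the fall of respiratory chain and mitochondrial ribosomal protein genes in low iron, beside a median signal of rRNA control probe sets that differed by -916 between low and high iron. A bias that depends on signal is argued against, since 0% of 10000 random lists matched on mean signal had a median as low as -1.15 or as -0.31, and the central 95% of such medians ran from -0.16 to 0.09 and from -0.10 to 0.05. A difference in labelling or RNA quality of low-iron arrays 1 and 2 alone is also argued against, because without them the medians were -1.10 and -0.29. From the 3' to the 5' end, control probe sets changed by -2.19, -2.48 and -2.74 for RIP1, -0.276, -0.31 and -0.35 for SPT15 and 0.122, 0.169 and 0.0697 for WBP1 on the log2 scale, and the 3' to 5' ratio of ACT1, itself near the top of the range, was 1.197 ± 0.0457 in low iron and 1.257 ± 0.0366 in high iron (SD, n = 4; exact permutation p = 0.114). Another difference in RNA between all low-iron and all high-iron cultures, and iron supply itself, remain open.

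The second pattern is the fall of pheromone response genes and of genes of MATa cells. Of the 22 pheromone response genes 21 fell, and a bias that depends on signal is argued against for the MATa list fixed beforehand, whose median of -0.48 was matched by 0% of 10000 random lists. Without low-iron arrays 1 and 2 the median of the pheromone genes was -1.20, against -1.21 with them. These genes were chosen after all arrays had been seen, so this value is no independent test. The median of the MATa list lay between -0.555 and -0.447 in all 24 alternatives, that without these arrays included. For the MATa genes this argues against these arrays as the source. A small share of MATalpha cells in the high-iron cultures, whose alpha factor could raise pheromone genes in the others, cannot be told apart from other causes. MF(ALPHA)1 had a log2 change of -2.21, but MF(ALPHA)2, STE3 and SAG1 had a median of -0.086. Whether the baseline signal of these 3 genes could hide a small share was not tested. An effect of iron supply stays open and untested.

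The third pattern is a signal outside the comparison. The 4 reporter-class probe sets with a mean over 100 reached 3144, 2255, 3034 and 532, and on low-iron array 1 and high-iron array 1 they read at most 25.9. A loss of signal across these arrays is argued against, since 0 of 82 other control or reporter-class probe sets with a mean signal over 100 lay more than 4-fold below the other 6 arrays on either one. The design gives no biological explanation, so none was tested, and the tables used here identify the sequences only by database numbers, with no gene named. All 4 were brightest on array 3 of each condition. A difference between cultures or strain stocks stays open and untested.

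Among 270 sets of 4 arrays tested for a value far from the others 14 stood out, where chance gives about 13.5. In low iron these were OPT2 at 13.2 and RNR2 at 3326 on array 1, MEP3 at 386 and ERG7 at 560 on array 1, CYC7 at 14.9 and SDH3 at 354 on array 2, FET3 at 4288 on array 3 and CTT1 at 25.7 on array 4. In high iron they were FIT3 at 1415 on array 1, FRE5 at 1.25 and ATX1 at 1121 on array 2 and CYC7 at 259 on array 3. The mean log2 signal of the tricarboxylic acid cycle list was 10.15 on low-iron array 1, where the others lay between 9.98 and 10.00, and that of mitochondrial ribosomal proteins was 9.63 on high-iron array 1, against 9.55 to 9.56. Of 404 probe sets without a gene name that lay above background 78 changed, 24 higher and 54 lower in low iron. These 404 were fitted and adjusted apart from the 5412 genes. Some may be S. pombe probe sets, since the arrays carry both species and no gene is named for them.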

How the results depend on the processing

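The settings that leave out 2 arrays and the replicate block were chosen after seeing the data. Counts of genes higher and lower in low iron stayed within 1.5 times of 907 and 1226 under each setting, from 694 to 1005 and from 993 to 1301 when single arrays were left out, 744 and 1113 without low-iron array 1 and high-iron array 1, and 805 and 1293 without low-iron arrays 1 and 2. Genes higher in low iron made up 42.5% of calls, and 52.0% under quantile normalization (1181 and 1091) and 51.5% under median centring (1138 and 1072). With the first 3 against the last 5 description numbers as a block the counts were 821 and 1086. The count of genes that differed at least 2-fold went from 223 to 135 with a pseudocount of 64, which shrinks the change of dim genes. Of 41 lists 16 passed, 1 with an estimated correlation and 26 with fry, which asks a different question. Directions of all 2133 called genes and of all 16 list medians were the same within the first 3 and within the last 5 description numbers, although the calls were made on the same arrays. Some values near 0 that had not passed changed sign: NDE2 (0.14), STE3 (0.26) and MF(ALPHA)2 (0.0044) under quantile normalization, STE3 when single arrays were left out (from -0.139 to 0.0130) and SAG1 without low-iron arrays 1 and 2 (-0.0054). The cytosolic ribosomal protein list turned to -0.028 under quantile normalization. The cause of these changes was not tested. Of 119 genes named, 110 kept their direction and side of the threshold under all 22 settings, 4 lost their call under at least 1, 1 gained it and 4 turned. The cytosolic ribosomal protein list was past the threshold and in its direction in 12 of 24 alternatives, the tricarboxylic acid cycle and nitrogen catabolite repressed lists in 17 each, ergosterol in 19 and purine and sporulation in 21 each. The labels give no shared replicate numbers and array numbers follow the order of deposit, but the 4 reporter-class probe sets with a mean over 100 were dark on array 1 and brightest on array 3 of both conditions. A fit with the array number as a replicate block, chosen after seeing the data, gave 714 genes higher and 1057 lower, with 16 lists past the threshold. It ended the call of the tricarboxylic acid cycle list (adjusted p = 0.0561), so these were not the same 16 lists as in the main fit. Deviations from the condition means of same-numbered arrays had correlations from -0.353 to 0.153 across genes, and 1 of 8 arrays correlated best with its own number, so these numbers were not taken to pair the cultures. Low signal over background limits the folds of dim genes, such as FRE5 and LSO1 in high iron.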

Other observations

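All genes and the list below were chosen after their values were seen. The list of 22 pheromone response genes was lower in low iron beyond the other genes, with a median log2 change of -1.21 (camera adjusted p = 7.63e-14; adjusted p = 0.0124 with an estimated correlation). Of these genes 21 fell and 1 rose, with the same counts when p-values were adjusted over the list alone. FUS1, needed for cell fusion during mating, fell 5.20-fold from 476 ± 14.2 in high iron to 91.7 ± 15.2 in low iron (SD, n = 4; limma adjusted p = 1.35e-07). AGA1, the anchor of the a-agglutinin, fell 3.91-fold from 1361 ± 94.8 to 347 ± 21.8, and PRM1, a membrane protein of cell fusion, read 172 ± 13.4 in high iron and 33.8 ± 3.94 in low iron, a log2 change of -2.31, or -1.27 on the log2(signal + 64) scale. PRM4 was the gene that rose, by 1.32 on the log2 scale. The list was drawn up because such genes stood out, so its test is no independent evidence.

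Several genes for oxidoreductases and detoxification, noticed among the larger changes and tested as no group, were higher in low iron on all 4 arrays than on any high-iron array. The nitroreductase-like genes FRM2 and HBN1 rose by 2.27 and 2.22 on the log2 scale, VMR1, a vacuolar ABC transporter, by 2.44, ZTA1, a quinone oxidoreductase, by 1.68 and CAD1, a transcription factor related to Yap1, by 1.36 (limma adjusted p between 2.01e-08 and 1.98e-05). Transcripts of 2 regulators also rose: AFT1, the iron-responsive transcription factor, 1.96-fold from 473 ± 10.6 to 933 ± 129, and HAP1, a haem-responsive transcription factor, 1.87-fold from 818 ± 12.3 to 1539 ± 201 (SD, n = 4; adjusted p = 2.59e-05 for both).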
